A study of Mus musculus with 12 samples.

How the data were processed

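Polyadenylated RNA from tumour-associated macrophages (TAMs) of 6 glioma-bearing mice was sequenced on an Illumina HiSeq 2500. Per the labels, each mouse gave 1 rhodamine-positive and 1 rhodamine-negative sort, which makes 12 libraries in 2 groups of 6, and every library carries the same batch label. Mice 1 to 4 are labelled male and mice 5 and 6 female.

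The authors deposited a table of raw read counts per gene, 1 count file per library and a table of log2 normalized values. Per the submitters' processing notes, bcl2fastq 2.17, cutadapt, HISAT2 2.1.0, featureCounts 1.4.4, edgeR and limma were used with genome build mm10. The notes, as used here, give neither the role and parameters of each tool nor the strand setting of the counting, so reads from overlapping or antisense genes cannot be assigned with certainty. All 12 count files held the same values as the deposited count table. The deposited log2 table held 10605 genes. Its values equalled the log2 CPM of the count table, with 0.5 added to each count and 1 to each total, plus a constant per library between -0.107 and 0.175.

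Tests were run on the deposited counts as they stand. The table listed 54532 genes, of which 35308 had a count in any library. The filter of edgeR (filterByExpr by group, minimum count 10, minimum total 15) left 15014 genes, which held 99.8% of all counts. Library sizes were scaled by the trimmed mean of M values (TMM), and CPM values are TMM-scaled. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the mouse as a block, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Log2 fold changes are rhodamine-positive minus rhodamine-negative, and their standard errors (SE) were taken as the absolute log2 fold change divided by the square root of its F statistic. Log2 CPM for pair differences and principal components used a prior count of 2. Where a symbol named several genes, the one with the most counts was used. Coordinates and gene types came from the GENCODE vM21 annotation of the same mouse build, which held 15005 of the 15014 genes tested.

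The mouse was used as a block because the series description states that both sorts came from the same animals. As a check, deviations from the group means correlated between the 2 libraries of a mouse with r = 0.226, 0.207, 0.289, 0.0775, 0.302 and 0.450 for mice 1 to 6. The highest correlation with a library of the other sort from another mouse was 0.148 to 0.187, and the pair of mouse 4 lay below it, so this check did not bear out the pairing of that mouse. The correlation is across genes, which are not independent replicates. Libraries of a group were compared by a chi-square of their counts over genes with at least 20 counts. The lowest chi-square per degree of freedom was 17.5 in the rhodamine-negative and 20.8 in the rhodamine-positive group, so no library was a copy of another, and all 12 were counted separately.

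A total of 35 gene lists was fixed before the data were examined, along with the rule for the genes named, the tests and most of the other settings tried. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with adjustment over the 35 lists. The correlation estimated from the data and fry were run beside it. Member counts are given over all genes tested and adjusted over the list alone. Named genes were, in each direction, the 12 with the largest log2 fold change among those past the threshold, with a mean log2 CPM of at least 3 and the same direction in all 6 pairs. Predicted genes, Rik genes and immunoglobulin or T cell receptor segments were skipped. Up to 4 members of each list with the smallest p, genes of the sort gate and of the sex labels, and the 5 genes with the smallest p for the sex interaction were added. Further list members named in the text were chosen after their values were seen, and some genes that the rule names are not reported here. Library properties were compared between the sorts by an exact two-sided sign-flip test over the 6 mice, whose smallest possible p is 0.0312. Detected genes were counted after thinning each library to 13073189 counts.

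The procedure was tested on simulated counts with the means and library sizes of these libraries. Of 100 genes changed by 0.5 on the log2 scale, 37% were recovered, and of 100 changed by 1, 85%. False calls were 9 of 131, and a shifted list was the 1 list called. Simulated genes varied independently of each other, so the list test was not tried under correlation between genes. The changed genes all lay above a minimum mean count, so recovery of genes with few counts was not tried. Other settings covered a fit without the block, DESeq2 1.42.0, limma-voom with a fixed or random mouse term, limma on the deposited log2 table, other scalings and filters, a gene length correction, stricter thresholds, male mice alone and each mouse left out in turn. Corrections for GC content with gene length, and library size alone for the lists, were added after seeing the data.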

Results

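The data describe which transcripts differ between TAMs that did and did not take up nanoparticles in a living tumour. Mice with gliomas, labelled Ntv-a_Ink4a/Arf_KO, received an intravenous injection of rhodamine-labelled perfluoro-crown-ether nanoparticles, and tumours were taken 24 hours later. Cells positive for CD45 and CD11b, the general leukocyte and myeloid surface markers, were sorted by their rhodamine signal, with more than 2000 cells per sort. The gate as described also required cells to be negative for Ly6C, a monocyte marker, which the description lists 2 times. The 12 libraries, 2 from each of 6 mice, held 13073189 to 17379314 counts, with 13421387 to 16167832 in rhodamine-negative and 13073189 to 17379314 in rhodamine-positive libraries. The comparison asks how the expression profile of TAMs that took up nanoparticles differs from that of TAMs that did not.

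The labels of sex and sort gate were checked first. Xist, the transcript of the inactive X chromosome, had 0 to 6 counts in libraries of male mice and 2571 to 5067 in those of female mice. The Y-linked genes Ddx3y (438 to 947 counts in males), Kdm5d (137 to 329) and Eif2s3y (549 to 840) had at most 1 count in females. Ptprc, which encodes CD45, and Itgam, which encodes CD11b, were abundant in all 12 libraries, with 3864 to 9673 and 2538 to 6506 counts. Ptprc fell by 0.56 on the log2 scale in rhodamine-positive sorts (SE 0.08, n = 6 pairs). Its estimate was -0.17 with an uncentred offset for GC content and gene length, which moved the median of all genes to 0.14 on the log2 scale. With that offset Ptprc did not pass the test (adjusted p = 0.093). In contrast, Itgam differed by 0.11 ± 0.11 (SE) and did not pass the test, and its estimate was -0.050 with scaling to library size alone. Ly6c2, a marker of inflammatory monocytes, had 0 to 154 counts, and Ly6g, a neutrophil marker, had 1 count over all libraries.

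TAMs that carried nanoparticles and those that did not separated along the first principal component, which held 34.7% of the variance. Nanoparticle-positive sorts had higher transcript levels of lysosomal, lipid-handling, iron-handling and cell cycle genes, and lower levels of MHC class II, dendritic cell, monocyte and cytokine genes. These lists passed camera with its preset correlation, and none of the 35 lists passed when it was estimated from the data (lowest adjusted p = 0.0678 with an estimated correlation). Gpnmb (ENSMUSG00000029816), a glycoprotein of lipid-laden phagocytes, rose most among the named genes, by 5.85-fold, from 136 ± 71.1 to 793 ± 436 CPM (SD, n = 6). Clec10a (ENSMUSG00000000318), a galactose-type lectin of dendritic cells and macrophages, fell by 3.50 on the log2 scale (SE 0.12), from 80.8 ± 27.8 to 6.98 ± 1.48 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3941 of 15014 genes passed, 1955 higher and 1986 lower. The larger changes were mostly decreases: 94 genes were at least 2-fold higher and 821 at least 2-fold lower, and at 4-fold the counts were 7 and 278. The direction was shared by all 6 mice for 1638 of the higher and 1618 of the lower genes. Scaled to library size alone, which moved the median of all genes to -0.18 on the log2 scale, the split was 852 higher and 3142 lower. Without the mouse as a block, 1270 genes were higher and 1398 lower.

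**Figure D1:**
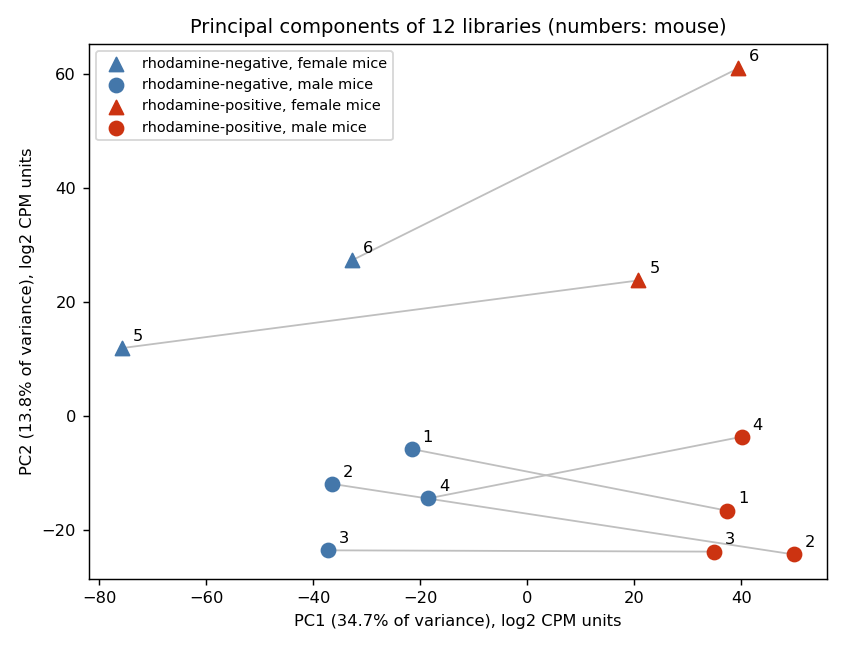
Principal components of the log2 CPM of the 12 libraries, with the share of variance on each axis; colours give the sort, symbols the sex, numbers the mouse, and grey lines join the sorts of a mouse. All 6 rhodamine-positive libraries lie between 20.8 and 49.8 on the first axis, all 6 rhodamine-negative ones between -75.7 and -18.5, and the lowest is mouse 5.

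The other 11 named genes that rose included Saa3, an acute-phase protein, and Cd5l, a scavenger receptor family protein secreted by macrophages. Saa3 rose 4.53-fold and Cd5l 3.36-fold. Spp1, which encodes osteopontin, went from 1039 ± 447 to 3109 ± 1513 CPM, and Fabp5, a fatty acid-binding protein, from 249.6 ± 83.0 to 681 ± 176 CPM (SD, n = 6). Cdo1, a cysteine dioxygenase, rose by 1.67 ± 0.14 (SE), the carbonyl reductase Cbr2 by 1.58 ± 0.18, the chemokine Ccl8 by 1.53 ± 0.24 and the mitochondrial protein gene Chchd10 by 1.41 ± 0.18 on the log2 scale. Lrrc27 and Sorbs3 rose by 1.41 ± 0.16 and 1.28 ± 0.22. Cbr2 and Ccl8 did not pass without the mouse as a block (adjusted p = 0.0657 and 0.07). The microRNA gene Mir692-2 is listed at 2.44 ± 0.52, but a single library in each group stood far above the others (10.04 and 47.2 CPM) and it belongs to a multicopy family, so its value is uncertain. Gpnmb lies at chromosome 6, positions 49036546 to 49070929, and Spp1 at chromosome 5, positions 104435118 to 104441050 (mm10).

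Among the 12 named genes that fell were transcripts typical of other leukocytes. Jchain, the joining chain of secreted immunoglobulins, fell by 7.41 on the log2 scale (SE 0.56), from 18.6 ± 12.2 to 0.0860 ± 0.175 CPM. Mcpt8, a protease gene of basophils, changed by -6.12, Cyp11a1, an enzyme of steroid synthesis, by -5.81, and Hdc, the enzyme of histamine synthesis, by -4.81. Their levels differed widely between mice, with Hdc at 100.2 ± 125 CPM in rhodamine-negative and 4.13 ± 6.72 CPM in rhodamine-positive sorts (SD, n = 6). The log2 fold change was -3.40 for the dendritic cell lectin Cd209a, -3.46 for the cell fusion gene Dcstamp, -3.22 for the collagen receptor Ddr1, -3.16 for Plet1 and -3.15 for the cytokine Il6. It was -3.09 for Klrd1, which encodes CD94 of natural killer cells, and -3.06 for Ifitm6. Il6 also varied widely between mice, with 47.8 ± 61.0 CPM in rhodamine-negative and 3.23 ± 1.82 CPM in rhodamine-positive sorts (SD, n = 6). Its rhodamine-negative level was highest in mice 3 and 5, at 97.3 and 149.7 CPM. In mouse 4 it went only from 6.36 to 4.64 CPM. Clec10a lies at chromosome 11, positions 70156197 to 70170834, and Cd209a at chromosome 8, positions 3743397 to 3748984 (mm10).

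**Figure D2:**
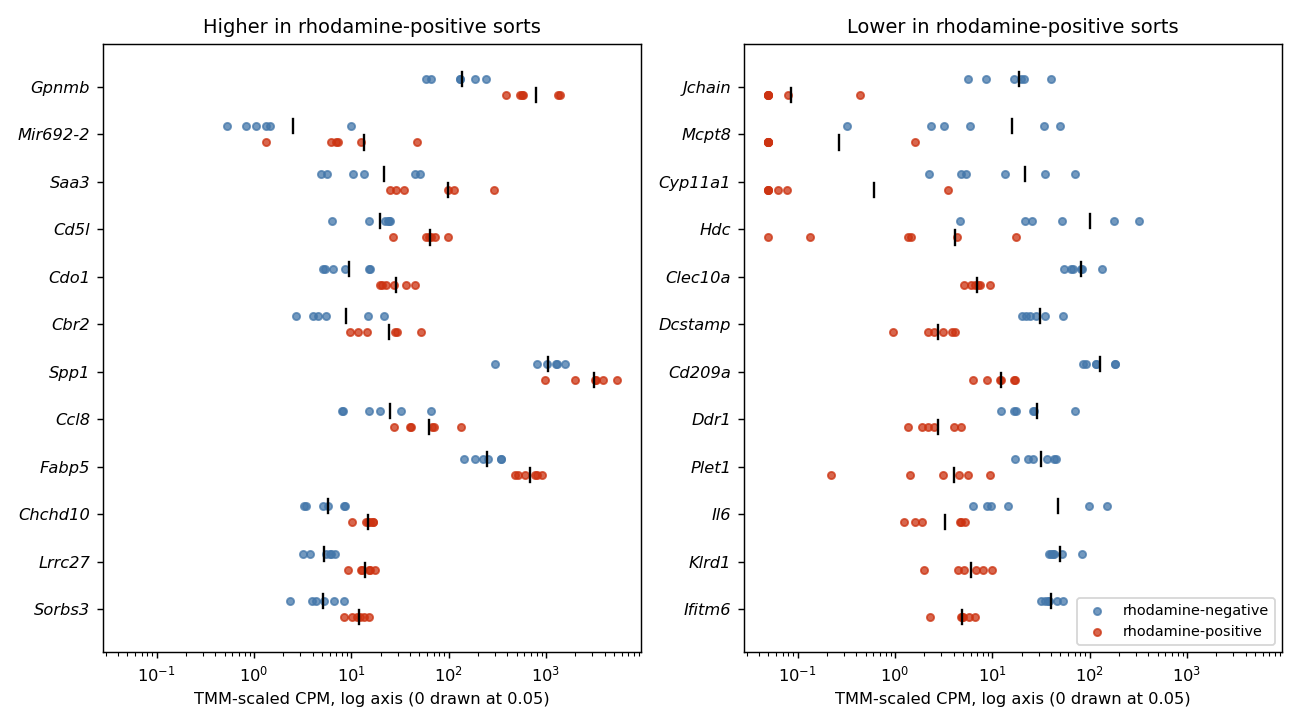
TMM-scaled CPM on a log axis of the 12 named genes in each direction; points are libraries, coloured by sort, and black bars are group means of 6. Values of 0 are drawn at 0.05, as for Jchain and Mcpt8 in rhodamine-positive libraries, and Gpnmb averages 136 and 793 CPM.

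Lysosomal genes, which encode the enzymes and membrane proteins of the degradative compartment that receives engulfed material, were higher in cells carrying nanoparticles. Of 33 measured members, 26 rose and none fell (28 rose when adjusted over the list alone), with a median log2 fold change of 0.59. The cathepsins Ctsd and Ctsb rose by 1.15 ± 0.14 and 1.10 ± 0.12 (SE), and Cd63 and Cd68, which encode endosomal and lysosomal membrane proteins, by 1.03 ± 0.15 and 0.87 ± 0.12. Cathepsin Ctss differed by 0.12 ± 0.11 and did not pass. The list passed camera (adjusted p = 2.27e-16), and its adjusted p = 0.134 with an estimated correlation.

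Uptake genes moved in both directions. Of 14 measured Fc and complement receptor genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone). C1qa, C1qb and C1qc, which encode the chains of complement C1q, rose by 0.65, 0.66 and 0.68, while Itgax, which encodes CD11c, fell by 1.00. The adjusted p of 0.000354 in camera became adjusted p = 0.415 with an estimated correlation. Of 33 genes of the endocytosis and macropinocytosis machinery, 13 rose and 4 fell (14 and 6 adjusted over the list alone), with a median of 0.15 that was -0.010 with library size alone. The clathrin adaptor genes Ap2s1 and Ap2m1 rose by 0.61 and 0.56, and the kinase gene Pak1 fell by 1.04. This list passed camera at adjusted p = 0.0411, with adjusted p = 0.436 with an estimated correlation and adjusted p = 0.121 with library size alone. It did not pass without mouse 1, 3 or 4 (adjusted p = 0.0928, 0.064 and 0.109). Of 20 scavenger and uptake receptors, 4 rose and 3 fell (4 and 3 adjusted over the list alone) and the list did not pass (camera adjusted p = 0.314). It passed, as higher, without a filter (camera adjusted p = 0.00479). In that setting the median of all genes was -0.315 on the log2 scale, and camera compares a list with the other genes. A pass as higher there does not show that the list itself rose. Msr1, Stab1, Scarb2 and Lrp1 were the 4 that rose, by 0.95, 0.92, 0.53 and 0.57.

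Lipid and iron metabolism genes were higher. Of 21 lipid handling and foam cell genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.47. Beside Gpnmb, Fabp5 and Spp1, these included Fabp3, a fatty acid-binding protein, at 1.27 ± 0.19 (SE), and Lipa, the lysosomal acid lipase, at 0.63 ± 0.08. The list had camera adjusted p = 8.76e-10 and adjusted p = 0.0819 with an estimated correlation. Of 16 iron and heme genes, 11 rose and none fell, also when adjusted over the list alone. The heme oxygenase Hmox1 rose 2.39-fold, the ferritin light chain Ftl1 1.95-fold and the heme transporter Slc48a1 1.74-fold. The camera adjusted p was 2.05e-08, with adjusted p = 0.0933 with an estimated correlation. Of 15 genes of the oxidative stress response driven by NRF2, 5 rose and 1 fell (7 and 2 adjusted over the list alone), among them Prdx1 at 0.68 and Hmox1, which the iron list shares. That list had camera adjusted p = 0.00547 and adjusted p = 0.202 with an estimated correlation. Of 22 cholesterol synthesis genes, 4 rose and 6 fell (4 and 8 adjusted over the list alone), with Pmvk at -0.78 and Fdft1, the squalene synthase, at 0.65, and the list did not pass (camera adjusted p = 0.338).

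Energy metabolism genes rose by small amounts. Of 21 oxidative phosphorylation genes, 18 rose and none fell (20 adjusted over the list alone), with a median of 0.36. The ATP synthase genes Atp5a1 and Atp5b rose by 0.52 and 0.47. The list had camera adjusted p = 7.91e-08 and adjusted p = 0.184 with an estimated correlation. Of 22 hypoxia and glycolysis genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone). Those that rose included the glycolytic enzymes Pkm at 0.68 and Eno1 at 0.54. The 3 that fell were Pfkp, also a glycolytic enzyme, at -1.73, and the hypoxia-inducible Ndrg1 and Vegfa. Glycolysis and hypoxia genes were not tested apart. This list had camera adjusted p = 0.000928 and adjusted p = 0.259 with an estimated correlation.

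All 24 measured cell cycle genes rose, over all genes tested and adjusted over the list alone. The median was 0.82, or 1.77-fold, and the list median was higher in 6 of 6 mice. The mitotic kinase gene Plk1 rose from 18.4 ± 3.17 to 40.1 ± 7.78 CPM (SD, n = 6), and Ccna2, Top2a and Ccnb1, which act in DNA replication and mitosis, rose by 0.88, 0.91 and 0.94. Camera gave adjusted p = 1.11e-23, with adjusted p = 0.0818 with an estimated correlation. In the same sorts, glioma and oligodendrocyte lineage genes were lower, with 9 of 15 falling (11 fell and 1 rose adjusted over the list alone) and a median of -1.13. Pdgfra, a receptor of oligodendrocyte precursors, fell by 2.11, and Mbp, a myelin protein, by 0.68. That list had camera adjusted p = 0.00204, with adjusted p = 0.454 with an estimated correlation.

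Genes of MHC class II antigen presentation were lower in cells carrying nanoparticles, and all 11 measured members fell, also when adjusted over the list alone. The median was -1.95, or 3.87-fold lower, and the list median was lower in 6 of 6 mice. Ciita, the master transactivator of the class II genes, fell by 2.80 ± 0.16 (SE). The class II chain genes H2-Eb1 and H2-Aa changed by -2.14 and -2.13, H2-Ab1 fell from 8585 ± 2943 to 1982 ± 648 CPM (SD, n = 6), and the invariant chain Cd74 fell from 10154 ± 4546 to 2552 ± 943 CPM (SD, n = 6). The smallest change was in the costimulatory gene Cd86, which fell by 0.38. Camera gave adjusted p = 8.31e-36, with adjusted p = 0.0678 with an estimated correlation. Of 11 dendritic cell markers, 9 fell and 1 rose, also when adjusted over the list alone, with a median of -2.23. The integrin gene Itgae and the growth factor receptor gene Flt3 fell by 2.52 and 2.36, and Sirpa, which macrophages also express, was the 1 that rose. The dendritic list had camera adjusted p = 2.1e-14, with adjusted p = 0.0678 with an estimated correlation. Of 11 MHC class I genes, 2 fell and none rose (1 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.873). Its direction in camera and its mean were negative while its median was 0.04.

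**Figure D3:**
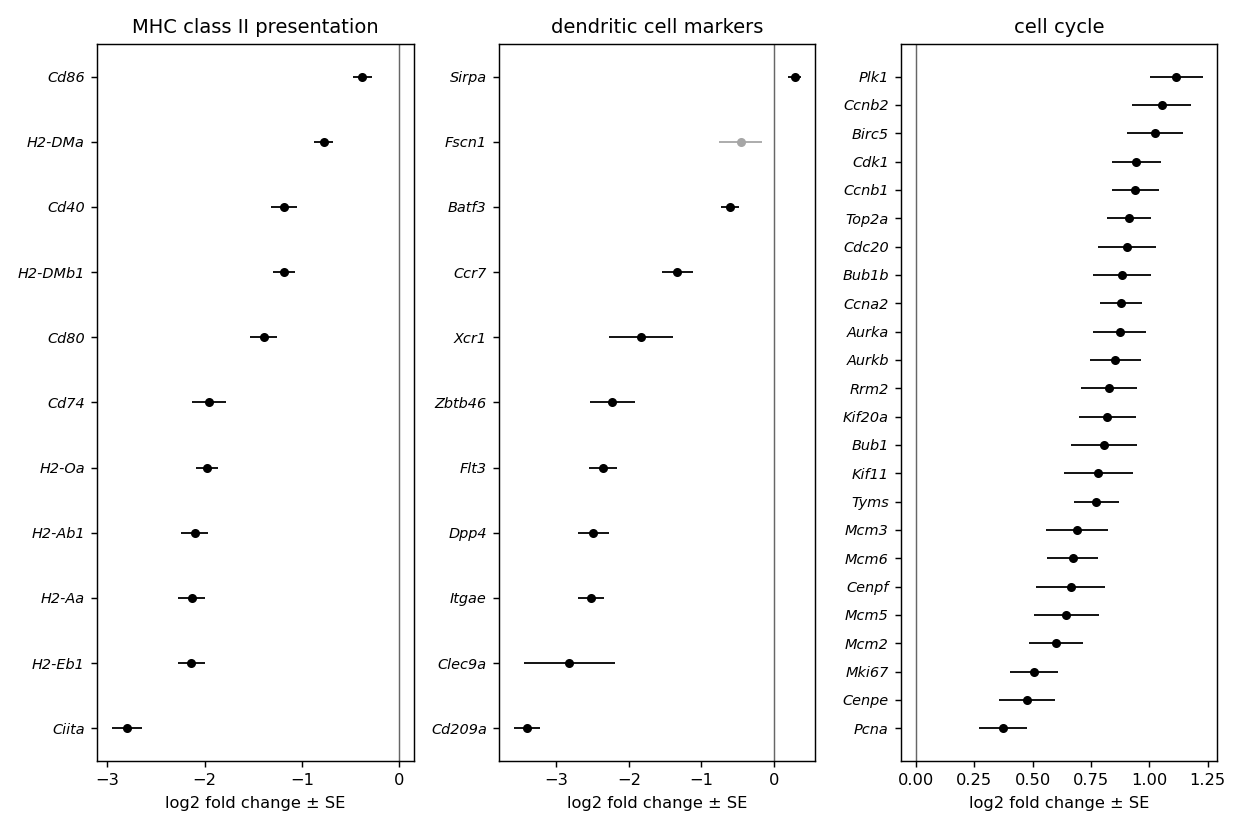
Log2 fold change with its SE (n = 6 pairs) of each measured member of 3 lists, rhodamine-positive minus rhodamine-negative; black points passed the test over all genes and grey points did not. All 24 cell cycle genes and all 11 MHC class II genes passed, with Plk1 at 1.12 and Ciita at -2.80.

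Markers of macrophage origin went in different directions. Of 17 markers of monocyte-derived macrophages, 10 fell and 1 rose, also when adjusted over the list alone, with a median of -0.74. Ccr2, the chemokine receptor of monocytes, fell by 2.51, Plac8 by 2.83 and the calcium-binding protein gene S100a6 by 2.48, while Lgals3, also in the lipid list, was the 1 that rose. Dendritic cell and NK cell markers, the latter with only 3 measured members, were lower in the same sorts. Their medians were -2.23 and -2.70, with camera adjusted p = 0.0678 with an estimated correlation for both. For the monocyte-derived macrophage list the camera adjusted p was 2.77e-13, with adjusted p = 0.0933 with an estimated correlation. Of 8 monocyte markers, 3 fell and none rose (4 fell adjusted over the list alone; camera adjusted p = 7.58e-05, and adjusted p = 0.134 with an estimated correlation). Of 9 border-associated macrophage markers, 7 rose and none fell (8 rose adjusted over the list alone). Siglec1, a sialic acid-binding lectin, and Stab1, a scavenger receptor, rose by 1.02 and 0.92. That list had a median of 0.83, camera adjusted p = 2.65e-07 and adjusted p = 0.0933 with an estimated correlation. Of 13 microglia markers, 3 rose and none fell, also when adjusted over the list alone. P2ry13 and Fcrls were among those that rose, by 0.49 and 0.51, and the list did not pass (camera adjusted p = 0.0842). P2ry13 and Fcrls did not pass with library size alone (adjusted p = 0.0805 and 0.087), and the list passed, as higher, without a filter and without mouse 1, 4 or 6 (adjusted p = 0.00225, 0.0309, 0.0223 and 0.0329). Without a filter the median of all genes was -0.315 on the log2 scale.

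Cytokine and activation genes were lower. Of 21 inflammatory cytokines and NF-kB targets, 10 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.45. The interleukin gene Il1b fell from 1257 ± 203 to 336 ± 73.2 CPM (SD, n = 6), and Nfkbia, an inhibitor of NF-kB, fell by 0.72. Dissociation and immediate early genes, used as a check of cell handling, were lower in the same sorts. Their median was -0.74, with camera adjusted p = 0.0678 with an estimated correlation. For the cytokine list camera gave adjusted p = 2.83e-05, with adjusted p = 0.134 with an estimated correlation. Of 15 alternative activation genes, 7 fell and 2 rose (7 and 3 adjusted over the list alone). Beside Clec10a, the lectin gene Mgl2 and the chemokine genes Ccl17 and Ccl22 fell by 2.52, 2.45 and 1.69, whereas Arg1, which encodes arginase, was 1 of the 2 that rose, by 0.62. The list median was positive in mouse 4, at 0.29, and negative in the other mice. Dendritic cell markers were lower in the same sorts, with a median of -2.23 and adjusted p = 0.0678 with an estimated correlation. The alternative activation list had camera adjusted p = 8.82e-07, with adjusted p = 0.134 with an estimated correlation. Of 20 genes of the type I interferon response, 6 fell and 1 rose (9 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0734). It passed, as lower, with library size alone, without a filter, in males alone and without mouse 3 or 6 (adjusted p = 0.0219, 0.0329, 0.0437, 0.0228 and 0.0154).

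**Figure D4:**
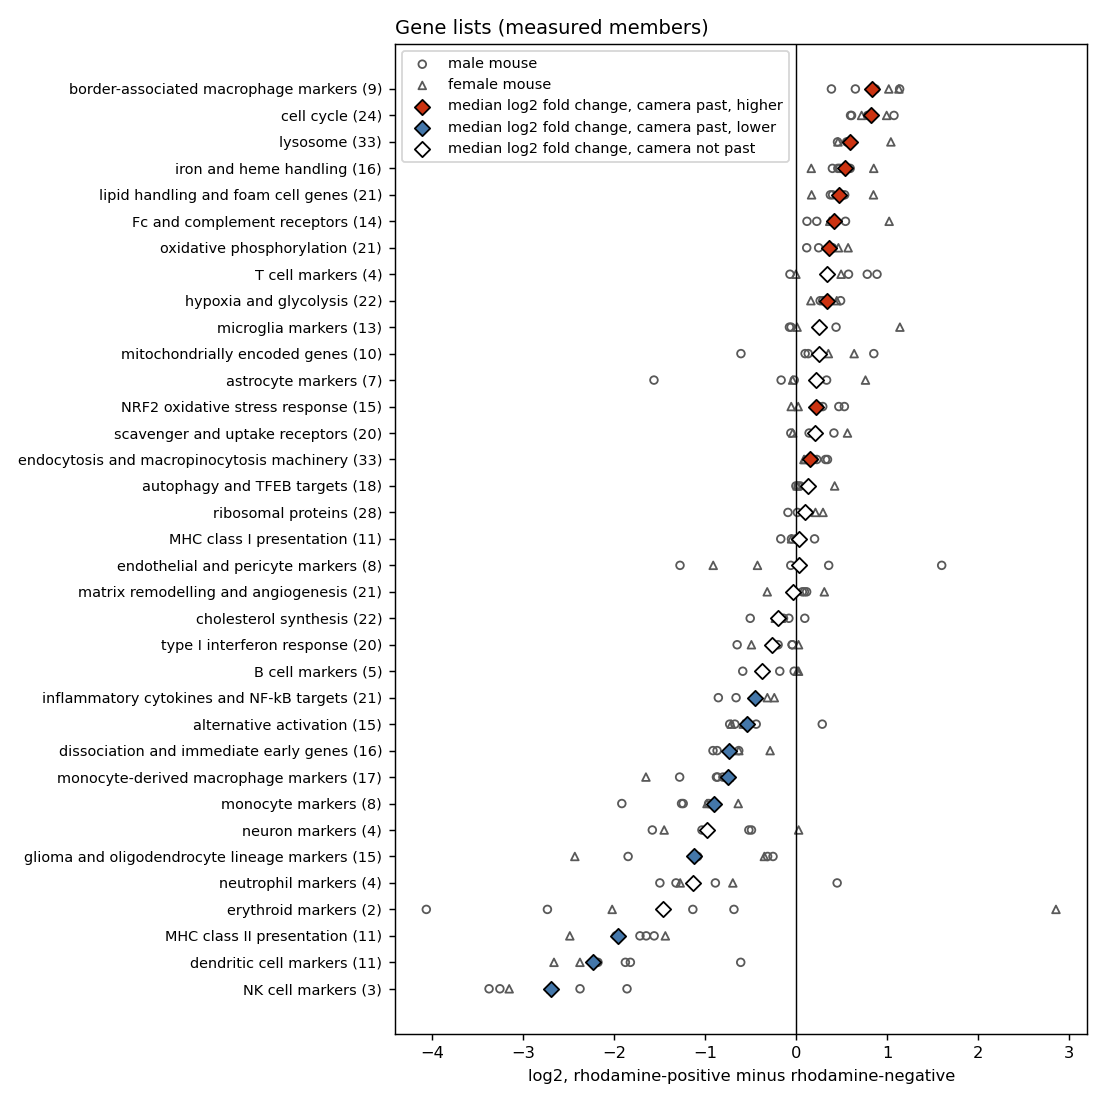
Median log2 difference, rhodamine-positive minus rhodamine-negative, of the 35 gene lists, with the number of measured members in brackets. Diamonds are medians of the fitted log2 fold changes, coloured where camera passed with its preset correlation, and open symbols are the medians of each of 6 mice. NK cell markers had the lowest median, -2.70, over only 3 measured members, and border-associated macrophage markers the highest, 0.83.

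Lists and library measures used as checks of handling and cell purity also differed between the sorts. Handling as a cause was not tested. Of 16 dissociation and immediate early genes, 13 fell and none rose (14 fell adjusted over the list alone), with a median of -0.74. Btg2 fell by 1.22 and Hspa1b, a heat shock gene, by 1.32. The camera adjusted p was 3.25e-12, with adjusted p = 0.0678 with an estimated correlation. Rhodamine-negative libraries detected more genes at equal depth, 23950 ± 474 against 20460 ± 803 (SD, n = 6), in 6 of 6 mice (exact two-sided sign-flip p = 0.0312, adjusted p = 0.0562 over 9 library measures). Of 10 NK cell markers only 3 passed the filter, and all 3 fell, also when adjusted over the list alone. Klrk1 changed by -2.47, Gzmb by -5.44 from 9.52 ± 11.6 CPM, and Klre1 by -2.70 from 1.31 ± 0.396 CPM (SD, n = 6). Ncr1, Prf1 and the remaining members were not among the genes that passed the low-count filter, so the list does not show NK cells as the source. This list had camera adjusted p = 5.88e-07, with adjusted p = 0.0678 with an estimated correlation. The mitochondrially encoded genes made up 0.699 ± 0.217% and 0.710 ± 0.154% of counts (SD, n = 6), and none of their 10 measured genes passed (camera adjusted p = 0.163). Ribosomal protein genes did not pass as a list (camera adjusted p = 0.0647), with 2 of 28 rising and 0 adjusted over the list alone. The mitochondrial list passed, as higher, without mouse 4, without a filter and with both offsets for GC content and gene length (adjusted p = 0.00278 to 0.00928). The list of ribosomal proteins passed, as higher, without mouse 1 or 4, without a filter and with the uncentred offset (adjusted p = 9.54e-06 to 0.0342), and its median was -0.060 with library size alone. For both lists, the fit without a filter had a median of all genes of -0.315 on the log2 scale.

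With the preset correlation 19 of 35 lists passed, 10 higher and 9 lower. With the correlation estimated from the data 0 of 35 passed after adjustment and 13 at an unadjusted p under 0.05, and fry, which tests each list by itself, called 19.

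Whether the contrast depended on sex was tested with the interaction of sort and sex, in 4 male and 2 female mice. In edgeR's quasi-likelihood test 0 of 15014 genes passed after Benjamini-Hochberg adjustment, with a lowest adjusted p of 0.562, and 1160 genes (7.73%) had an unadjusted p under 0.05. DESeq2 called 28 genes, a quasi-likelihood fit without a filter 119 and limma-voom 0. The unfiltered fit took in 35308 genes, with a lowest adjusted p of 4.28e-19 from the same 2 female pairs. Its calls hinge on the filter and do not show a sex difference. The smallest p in the filtered fit belonged to Tmem123, Ahr, Igkc, Ccl2 and Nbeal2, of which all 5 passed without a filter and 4 with DESeq2. Ahr, the aryl hydrocarbon receptor, had a mean pair difference of -3.24 on the log2 scale in the 2 females and -1.39 ± 0.36 (SD, n = 4) in the males. Ccl2, a monocyte chemokine, had 1.36 and 0.20 ± 0.30. Without mouse 6, which leaves a lone female pair assumed to vary like the males, 4 genes passed (Lars2, Gm23935, Gm15564 and Jak2), all named after their values were seen.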

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

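The tests of tumour cells and both tests of dilution in the cell cycle pattern were chosen after the result was seen, as was the centring of the GC content correction. Of 105 groups of 6 values examined for a value far from the others, 14 had one. The rule would flag about 1 in 20, or 5.25, among independent normal values. CPM values with many zeros are not normal and many groups share libraries, so 14 is not shown to exceed chance.

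Mouse 5 accounted for 8 of these values. Its rhodamine-negative library had a TMM factor of 1.146 (the others 1.022 to 1.063), Ddr1 at 71.3 CPM (12.2 to 27.0) and Klrd1 at 82.8 CPM (37.9 to 51.3). Its rhodamine-positive library had Mcpt8 at 1.59 CPM where the others had 0, Cyp11a1 at 3.53 CPM (at most 0.0776 in the others) and Hdc at 17.5 CPM (at most 4.35). Its median pair difference was 1.04 for the lysosome list (0.45 to 0.59 in the other mice) and 0.42 for autophagy and TFEB targets (-0.0033 to 0.13). Without mouse 5, 3162 genes passed. In other mice, Mir692-2 stood at 10.04 CPM in the negative library of mouse 1 and at 47.2 CPM in the positive library of mouse 2. Saa3 stood at 294.9 CPM in the positive library of mouse 4, Jchain at 0.437 CPM in that of mouse 2 and Ly6c2 at 6.90 CPM in that of mouse 6. The alternative activation list had a median of 0.29 in mouse 4, against -0.73 to -0.44 in the others. B cell markers had medians below 0 in all 4 males, the nearest at -0.022, and just above 0 in both females, at 0.013 and 0.026. The female minus male mean was 0.31 on the log2 scale, 1 such case among 67 comparisons, and the difference was not tested.

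Basophil and plasma cell transcripts were lower in rhodamine-positive sorts. The basophil and plasma cell lists used here were not among those fixed before the data were examined. They were fitted without the low-count filter, a setting in which the median of all genes was -0.315 on the log2 scale. Over the basophil list the median log2 fold change was -4.30, with all 8 genes lower adjusted over the list alone. Over the plasma cell list it was -2.31, with 7 of 9 lower. Some members had few counts, such as Cpa3 with 60 over the rhodamine-negative and 6 over the rhodamine-positive libraries. In rhodamine-negative libraries the most abundant basophil genes were Gata2 and Il4, and the most abundant plasma cell gene was Iglc1. In rhodamine-negative and rhodamine-positive sorts Gata2 had 12.65 ± 15.3 and 0.450 ± 0.366 CPM (SD, n = 6). Il4 had 12.03 ± 16.2 and 0.351 ± 0.435 CPM, and Iglc1 3.20 ± 4.38 and 0.144 ± 0.315 CPM. Without mouse 5, whose rhodamine-negative library held the most basophil counts, Gata2 averaged 7.40 CPM there and the basophil median was -3.76. The CD11b gate would keep basophils, which carry this marker, and would remove most plasma cells, whose free RNA may still enter a sort. A few such cells in the rhodamine-negative sort are a candidate source for these transcripts, and no biological explanation was tested.

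MHC class II and dendritic cell genes fell together in rhodamine-positive sorts, which may come from dendritic cells in the rhodamine-negative sort or from macrophages with lower class II expression. Over the 6 mice the list medians had r = 0.396 (exact one-sided permutation p = 0.193) and Spearman's rho = 0.314 (exact one-sided permutation p = 0.282), and r was -0.541 without mice 4 and 5, which left the first open. The class II list fell by about as much as the dendritic list, with a mean difference of 0.115 ± 0.663 (SD, n = 6; exact two-sided sign-flip p = 0.656), as dendritic cells as the sole source would give. The spread is wide, so an unequal fall of the 2 lists could not be told from an equal one. The class II members also fell by unequal amounts, with Cd86 at -0.38, H2-DMa at -0.78 and Ciita at -2.80. The dendritic list shares Cd209a with the scavenger list, and macrophages express Sirpa as well. In this design a difference in uptake between cell types and one within macrophages cannot be told apart by the correlation across mice.

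Cell cycle genes were higher in rhodamine-positive sorts. Tumour cells carried along would raise glioma and oligodendrocyte lineage genes, whose median was -1.13, so the data argue against them. With GC content and gene length trends removed, 100% of the 24 called genes stayed past the threshold, with a median of 0.83 against 0.82 before. Dilution of all macrophages alike by other cells in the rhodamine-negative sort would raise microglia markers as much. Their median was 0.25 with an SD of 0.26 over 13 members, below the cell cycle median of 0.82. Members of a list are not replicates, so this gap does not decide the question. Over mice the question was not settled. The cell cycle list exceeded the microglia list by 0.513 ± 0.473 (SD, n = 6, 5 of 6 mice, exact two-sided sign-flip p = 0.0625). In mouse 5 the microglia median was the higher, 1.14 against 0.99. Dilution of a part of the macrophages stayed open as well. The cell cycle list exceeded the Fc and complement receptor list by 0.345 ± 0.366 (SD, n = 6, 5 of 6 mice, exact two-sided sign-flip p = 0.0625). No biological explanation was tested.

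For the count of genes, the real split stood alone, but the splits of the 12 libraries are not a clean test of chance. Each other split leaves the real sort difference within its groups, which widens the spread and would lower the count of genes. Splits that part all pairs and keep 10 libraries as in the real one gave 14 to 22 lists but 0 genes. Of 32 splits that part all 6 pairs, 1 gave 3941 genes or more, the real one, and the highest of the others was 0. Of 69 splits, the real one and 68 drawn from those that part only some pairs, 1 gave as many, and the highest other had 838. For the 19 lists these splits could not exclude chance, but they are not a clean test of it. At least as many passed in 5 of 32 splits, with 23 in the highest other, and in 18 of 69, with 22 in the highest other. All of these other splits kept 8 or 10 of the 12 libraries grouped as in the real one and so carry part of its difference. Splits that kept only 6 gave 1 to 13 lists where all pairs are parted (10 splits) and 0 to 8 where some are (27 splits).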

How the results depend on the processing

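The corrections for GC content and the lists scaled to library size alone were chosen after seeing the data. The call of 3941 genes (1955 higher, 1986 lower) was 1941 (908 and 1033) at an adjusted p under 0.01, 523 (70 and 453) against a fold change of 1.5, 2227 (1005 and 1222) in male mice alone and 2678 to 3600 with each mouse left out. Leaving out a mouse gave 1257 to 1780 higher genes, the lowest without mouse 3, and 1421 to 1820 lower ones. Without the block pairing each mouse, 2668 genes passed, with 1270 higher, and the block moved no list count and no sex count. Library size alone gave 852 higher and 3142 lower. Offsets for gene length, and for GC content and length, gave 4033 and 4066 higher genes and moved the median of all genes to 0.15 and 0.14; with the offset centred, 2087 were higher. With DESeq2 3876 of the 3941 calls passed and with limma-voom 3871. The count of 19 lists was 0, with 0 higher and 0 lower, with an estimated correlation, and 19 to 22 with a mouse left out (9 to 12 higher, 9 to 11 lower). The sex count of 0 was 119 without a filter, 28 with DESeq2 and 0 to 4 with a mouse left out. Signs turned only where the reported value had not passed, apart from 1 list (endocytosis and macropinocytosis machinery, -0.010 with library size alone). That scaling also gave -0.050 for Itgam, -0.12 for MHC class I presentation, -0.028 for autophagy and TFEB targets, -0.060 for ribosomal proteins and -0.13 for endothelial and pericyte markers. B cell markers turned to 0.26 without the block and T cell markers to -1.66 without a filter. MHC class I presentation was -0.027 in males and -0.022 with the centred offset, where endothelial and pericyte markers were -0.0038, and matrix remodelling and angiogenesis was 0.038 in males and 0.13 with the GC content and length offset. With a mouse left out, medians ranged from -0.51 to 0.28 for endothelial and pericyte markers, -0.42 to 0.052 for B cell markers, -0.092 to 0.57 for astrocyte markers, -0.067 to 0.057 for matrix genes and -0.0011 to 0.050 for MHC class I genes. The cause of these changes was not tested, except that a stricter threshold leaves fewer calls by construction. Depth limits genes with few counts, such as Mcpt8, which had 0 in all but 1 of the rhodamine-positive libraries.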

Other observations

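Of 4 measured T cell markers, Cd4 rose by 0.90 (SE 0.24), adjusted over the list alone as well, and macrophages of some tissues express it too (camera adjusted p = 0.352). The list of T cell markers passed, as lower, without a filter, with a median of -1.66 (adjusted p = 0.0386), against the direction of Cd4. Of 5 B cell markers, Cd22 rose by 0.95 and Ighm fell by 0.38, both also adjusted over the list alone, and the list's median was -0.38 while camera gave a positive direction (adjusted p = 0.664). Of 4 neutrophil markers, 1 rose and 2 fell, Cxcr2 by 2.42 (camera adjusted p = 0.369). Of 7 astrocyte markers, S100b rose by 0.70 and the enzyme gene Aldoc fell by 1.39, with a median of 0.22 against a negative mean and camera direction (adjusted p = 0.621). Of 4 neuron markers, Tubb3 and Map2 fell by 2.21 and 1.53 (camera adjusted p = 0.35). None of 8 endothelial and pericyte markers passed (adjusted p = 0.992), nor of 2 erythroid markers (adjusted p = 0.401). The erythroid markers passed as a list, as lower, without mouse 6 (adjusted p = 0.0473). Their median was 2.85 in mouse 6 and -4.06 to -0.68 in the other 5 mice. Cd4 did not pass without mouse 3 (adjusted p = 0.0548), and Ighm, S100b, Tubb3 and Map2 did not pass without mouse 2 (adjusted p = 0.079, 0.0629, 0.056 and 0.0866).

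Of 21 matrix remodelling and angiogenesis genes, 7 rose and 4 fell, also when adjusted over the list alone, with a median of -0.03 and a positive camera direction (adjusted p = 0.35). Spp1 and the matrix protein gene Ecm1 were among those that rose and the growth factor genes Hbegf and Vegfa among those that fell, by 1.31 and 0.79. Of 18 autophagy and TFEB target genes, Fnip2 and Atg7 rose by 0.65 and 0.41 and Uvrag fell by 0.71, also when adjusted over the list alone (camera adjusted p = 0.29). The list of autophagy and TFEB targets passed, as higher, without a filter (camera adjusted p = 0.00479), where the median of all genes was -0.315 on the log2 scale. The 10 most abundant genes took 15.1 ± 1.67% of counts in rhodamine-positive and 11.3 ± 1.00% in rhodamine-negative libraries (SD, n = 6), higher in 6 of 6 mice (exact two-sided sign-flip p = 0.0312, adjusted p = 0.0562). Apoe alone, a lipid carrier, took 4.02 ± 1.28% and 3.01 ± 1.10%, higher in 5 of 6 mice (exact two-sided sign-flip p = 0.0625, adjusted p = 0.0938).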
